A study of Arabidopsis thaliana with 24 samples.

How the data were processed

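RNA was sequenced from the shoot apex and the true leaves of Arabidopsis thaliana (Col-0) seedlings. Per the labels' protocols, plants grew for 14 days in 12 h light and 12 h dark, were moved to constant light and were sampled 90, 94, 98, 102, 106 and 110 h later. For each sample 6 to 10 seedlings were frozen and dissected, and polyA RNA was sequenced as single-end 50 bp reads. There were 24 libraries in 12 groups of 2, and the labels describe 2 independent experiments without saying which replicate number belongs to which. The deposited column names of all 24 libraries hold the word mock, and the labels describe no treatment.

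FPKM values for 33323 genes were deposited in 1 table, made by the authors from reads, and the submitters' processing notes name STAR 2.5.0c, HOMER and TAIR10 without their settings. The counting of reads shared between gene copies is not stated, and 49 tested genes shared all 24 values with another tested gene. The table held no organelle genes. A gene with a text cell in leaves ZT98 replicate 1 (AT1G73170) was left out. Read depth is not given, and from the step between FPKM values it was estimated at 7.7 to 14.9 M reads in the shoot apex and 11.1 to 14.5 M in leaves. The 10 most abundant genes took 3.7% to 4.9% of FPKM in shoot apex libraries and 9.2% to 16.2% in leaf libraries.

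Genes with FPKM of at least 1 in at least 2 libraries were tested as log2(FPKM + 1) with limma 3.58.1 (R 4.3.3, trended empirical Bayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The tissue difference was the mean of the 6 shoot apex groups minus that of the 6 leaf groups, and F-tests compared time points within a tissue and the interaction. Rhythms were tested as the cosine and sine terms of a 24 h wave per tissue over a window of 20 h. The difference of these terms tested the tissues against each other, and period was not estimated. With less than a full cycle sampled, a rhythm cannot be told from another smooth course over the window. Rhythmic, cycling and oscillating genes are those that passed this test. Standard errors of peak times came from the delta method. Lists were tested with limma camera (preset correlation 0.01, beside an estimated correlation and fry) for the tissue difference, and with Fisher exact tests for rhythm. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

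The comparisons, the 26 lists (421 genes, 381 tested, 1 left out for another name in the annotation) and the alternatives were fixed before the data were examined, except where a text says otherwise. The lists were clock morning, clock evening, clock output, meristem and boundary, leaf primordium, flowering, floral identity, mitosis, DNA replication, ribosome, photosynthesis, starch, flavonoid, glucosinolate, heat shock, cold, rapid stress, jasmonate, salicylate defence, auxin, cytokinin, gibberellin, senescence, stomata and trichome, vascular and root. Genes were named by a rule. It took the 10 with the largest tissue difference in each direction (mean FPKM of at least 10 in the higher tissue, one sign at all 6 time points), the 8 with the largest amplitude per tissue (mean FPKM of at least 5 there) and the 10 with the smallest adjusted p for a rhythm difference (mean FPKM of at least 5 in both tissues). It also took clock genes, up to 4 members per list with the smallest adjusted p, and members against their list's majority (all where there were up to 4 in the tissue comparison, otherwise examples). The result of 1 list member is not reported here.

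Alternatives were a pseudocount of 0.1, no filter, a stricter filter (mean FPKM of at least 5), rescaled libraries (median ratio to the geometric mean), the replicate number as a block, periods of 22 and 26 h, each tissue alone, robust empirical Bayes, and leaving out each library or replicate number. A replicate block within each tissue was added after seeing the data. Whether replicate numbers pair the samples was checked from the correlation of replicate differences between groups. It was 0.16 to 0.44 within the shoot apex, 0.55 to 0.76 within leaves and -0.01 to 0.32 between tissues. Between tissues at the same time point it was 0.05 to 0.32 (median 0.2). Numbers thus pair time points within a tissue, and any pairing of the tissues was weaker.

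The fits were tested on simulated data for 19986 genes, with known changes in some of them. The noise was normal and independent between genes and libraries, without a replicate difference. Changes were set in genes above a minimum mean level, and rhythms were exact 24 h waves. The recovery and false calls describe that setting and may be less favourable in the real libraries. For the tissue difference, 87% of genes changed by 0.5 log2 and 97% of those changed by 1 were recovered, with 16 calls among 19786 unchanged genes. Rhythms of amplitude 0.5 were recovered in 93.5% of cases in the shoot apex and 92% in leaves. For the rhythm difference, 75.5% of genes with an amplitude of 0.5 in 1 tissue and 6% of those with peaks 1 h apart were recovered.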

Results

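The design addresses how transcript levels differ between the shoot apex and the true leaves of Arabidopsis seedlings, and how the transcripts of each tissue move while the circadian clock runs freely in constant light. FPKM values are means ± SD over the 12 libraries of a tissue unless another n is stated. Tissue differences are log2(FPKM + 1), shoot apex minus leaves, with the standard error (SE) of the limma fit over all 24 libraries. Amplitudes are log2 units from the mean to the peak of a fitted 24 h wave (± SE), and peak times are hours after transfer to constant light, modulo 24.

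Transcripts of the growth coactivator GIF1 stood at 71.9 ± 7.41 FPKM in the shoot apex against 0.768 ± 0.396 in leaves, a log2 difference of 5.39 ± 0.10. CYP78A5, a cytochrome P450 gene known from the periphery of the meristem, was at 60.9 ± 12.4 FPKM in the shoot apex against 0.0787 ± 0.0624 in leaves. FTM1, a desaturase gene with known meristem expression, differed by 5.75 ± 0.10, and the arabinogalactan protein gene AGP31 by 5.66 ± 0.087. Log2 differences were 6.91 ± 0.16 for the cutinase gene CDEF1, 5.93 ± 0.18 for the lipid transfer protein gene LTP6, 5.02 ± 0.088 for the peroxidase gene PRXCA and 4.95 ± 0.072 for the carboxypeptidase gene scpl31. PRB1, a pathogenesis-related gene, differed by 5.53 ± 0.14 and the drought gene DI21 by 5.12 ± 0.15. Leaves held more transcript of the carbonic anhydrase genes CA1 and CA2, with log2 differences of -6.23 ± 0.14 and -5.75 ± 0.096. SWEET11, a sucrose exporter gene of the phloem, was at 0.0948 ± 0.0804 FPKM in the shoot apex against 80.9 ± 21 in leaves. The jasmonate synthesis genes LOX2 and AOC2 differed by -5.83 ± 0.18 and -5.53 ± 0.21. The aldolase gene FBA5 differed by -5.78 ± 0.18 and the cytochrome P450 gene CYP706A6 by -5.74 ± 0.049. The naming rule required the same sign at all 6 time points for each gene named so far. Their limma adjusted p was at most 2.63e-14 among the shoot apex genes and 3.25e-13 among the leaf genes. Among the leaf genes, PCR1 (cadmium resistance), LURP1 (defence) and ACD6 (cell death control) depended on the replicate number. Leaf means were 335 ± 154 FPKM in replicate 1 and 34.9 ± 32.3 in replicate 2 for PCR1 (SD, n = 6 each). They were 472 ± 136 and 125 ± 106 for LURP1 and 222 ± 76.6 and 114 ± 75.1 for ACD6.

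Of 19986 genes tested, 18003 differed between the tissues (limma, adjusted p under 0.05), 13720 higher in the shoot apex and 4283 higher in leaves. One sign in both replicate numbers was found for 17923 (99.6%). Differences of at least 2-fold were found for 5445 genes higher in the shoot apex and 1872 higher in leaves. The split depended on the scale of the libraries. The median log2 difference of all genes was 0.58 on the deposited scale and 0.023 after each library was rescaled by the median of its ratios to the gene-wise geometric mean. The share of called genes higher in the shoot apex moved from 76.2% to 51%. Relative to the shift of 0.58, 1954 of the called genes lay at least 2-fold above it and 3365 at least 2-fold below it.

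Meristem, cell cycle and ribosome genes were higher in the shoot apex. Among meristem and organ boundary genes, 19 of 20 were higher there and 1 (the receptor gene CLV1) did not pass but was lower there after rescaling, by -0.59. The knotted homeobox genes KNAT1 and STM stood at 27.2 ± 4.33 and 25.9 ± 4.38 FPKM against 0.0315 ± 0.0379 and 0.0331 ± 0.0572 in leaves, and LSH4 differed by 4.70 ± 0.063. All 18 mitosis genes were higher in the shoot apex, for example the cyclin gene CYCB2;2 by 2.59 ± 0.056 and the kinase gene CDKB1;1 by 2.74 ± 0.065. So were all 19 genes of DNA replication and cell cycle entry, for example CYCD3;3 by 3.08 ± 0.054, the clamp gene PCNA1 by 2.40 ± 0.052 and the helicase gene MCM4 by 2.07 ± 0.046. All 19 ribosome and nucleolus genes were higher in the shoot apex, among them NOP56 by 2.1 ± 0.041 and RPS6B by 1.43 ± 0.034. The median log2 differences of these 4 lists were 2.55, 2.64, 1.98 and 1.43, and 2.17, 2.05, 1.33 and 0.74 after rescaling. Of 21 leaf primordium genes, 17 were higher in the shoot apex (GRF5 by 4.57 ± 0.088, REV by 2.25 ± 0.049) and 4 TCP genes were higher in leaves (TCP3 by -1.47 ± 0.047, TCP4 by -0.69 ± 0.079, TCP10 by -0.41 ± 0.065 and TCP13 by -0.99 ± 0.11). The median was 1.71 (1.06 after rescaling), and the list test did not pass (limma camera adjusted p = 0.116; 0.633 with an estimated correlation). Of 13 cytokinin genes, 11 were higher in the shoot apex (CKX1 by 2.19 ± 0.053, ARR9 by 1.87 ± 0.065), 1 was higher in leaves (ARR16, -0.56 ± 0.095) and 1 did not pass. The median was 1.4 (0.84 after rescaling), and the list test did not pass (adjusted p = 0.116; 0.443 with an estimated correlation).

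Genes of photosynthesis and photorespiration were higher in leaves in 28 of 28 cases, with a median log2 difference of -2.60. The small rubisco subunit gene RBCS1B differed by -4.81 ± 0.081, rubisco activase (RCA) by -3.94 ± 0.066 and the photosystem gene PSBO2 by -3.19 ± 0.057. Copies of the rubisco subunit, LHCB1 and histone H3 genes are nearly identical, so how 50 bp reads were divided among them is uncertain. Of 19 starch genes, 15 were higher in leaves (the amylase gene BAM3 by -3.05 ± 0.061, GWD1 by -1.72 ± 0.067) and 2 did not pass. ISA3 and DPE1 were higher in the shoot apex (0.59 and 0.16) but fell to -0.03 and -0.47 after rescaling. Rapid stress genes, which respond to touch and wounding within minutes, were higher in leaves in 13 of 14 cases (TCH3 by -3.31 ± 0.35, ZAT10 by -2.22 ± 0.26), and 1 did not pass. Of 13 salicylate and defence genes, 12 were higher in leaves (PBS3 by -2.46 ± 0.48, CBP60G by -1.94 ± 0.32) and 1 did not pass. Of 13 cold response genes, 10 were higher in leaves (COR47 by -1.13 ± 0.12, COR15B by -2.79 ± 0.35), 2 in the shoot apex and 1 did not pass. The 2 were ERD10 and GOLS3 (0.74 and 0.93), of which ERD10 no longer passed after rescaling, at 0.06. The medians of these 4 lists were -0.66, -1.02, -1.65 and -0.80, and -1.32, -1.57, -2.24 and -1.44 after rescaling. On the deposited scale that of the cold list was -0.41 in replicate 1 and -1.07 in replicate 2.

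Other lists held members on both sides. Of 16 jasmonate genes, 8 were higher in leaves (AOS by -2.57 ± 0.067), 7 in the shoot apex (JAZ10 by 1.28 ± 0.11, VSP1 by 2.01 ± 0.27) and 1 did not pass. The median was -0.39 and the mean -0.87. Rescaling gave 10 higher in leaves and 3 in the shoot apex, with a median of -0.99. Of 10 vascular genes, 5 were higher in leaves (the phloem genes SWEET12 by -4.64 ± 0.11 and SUC2 by -3.21 ± 0.11), 4 in the shoot apex and 1 did not pass (median -0.13, mean -1.4). The 4 were the xylem and procambium genes ATHB8, XCP1, CESA7 and CESA8, with 1.06 ± 0.06, 0.39 ± 0.072, 0.34 ± 0.094 and 0.23 ± 0.082, and after rescaling the last 3 fell to -0.27, -0.21 and -0.32. Of 8 senescence genes, 5 were higher in leaves (SEN1 by -1.42 ± 0.17) and 2 in the shoot apex (WRKY53 by 1.89 ± 0.23, ORE1 by 0.53 ± 0.11), with a median of -0.78. Of 15 clock genes of the morning, 10 were higher in leaves (CDF1 by -1.45 ± 0.093), 1 in the shoot apex and 4 did not pass (median -0.24). The 1 was PRR7 (0.15 ± 0.053, but -0.46 after rescaling). With rescaled libraries all 15 were higher in leaves, with a median of -0.81. Of 9 clock output genes 6 were higher in leaves (CAT2 by -5.13 ± 0.085) and 3 in the shoot apex, GRP7, GRP8 and CO (0.95 ± 0.07, 0.55 ± 0.062 and 0.64 ± 0.076; median -0.64). After rescaling GRP8 fell to -0.14 and CO no longer passed, at 0.15. Auxin genes split into 6 higher in the shoot apex (YUC4 by 2.86 ± 0.063), 9 higher in leaves and 2 not passing. Their median was -0.27 and their mean 0.39, and the list test pointed down without passing (limma camera adjusted p = 0.0534; 0.443 with an estimated correlation). Gibberellin genes split into 9, 1 and 3 (RGA by 0.98 ± 0.037; GA3OX2, the 1 higher in leaves, by -0.41 ± 0.071; median 0.84). Glucosinolate genes split into 15 higher in the shoot apex (BCAT4 by 2.38 ± 0.099) and 5 higher in leaves (the myrosinase genes TGG1 and TGG2 by -2.77 ± 0.085 and -1.86 ± 0.096; median 0.87), and the list test found no difference from other genes (limma camera adjusted p = 0.924; 0.97 with an estimated correlation). Rescaling gave 10 glucosinolate genes higher in the shoot apex and 7 in leaves (median 0.27). For gibberellin genes it gave 7 and 4 (median 0.3). For 5 lists the median changed sign after rescaling. Clock genes of the evening (8 higher in the shoot apex and 5 in leaves, but 1 and 10 after rescaling) went from 0.17 to -0.38. TOC1 was at 1.02 ± 0.056 on the deposited scale. Flavonoid genes (8 and 5, rescaled 7 and 8) went from 0.36 to -0.32, with LDOX at 3.56 ± 0.19 and PAL1 at -1.31 ± 0.072. Flowering genes (9 and 5, rescaled 7 and 8) went from 0.41 to -0.26, with AGL24 at 2.3 ± 0.07 and FT at -0.63 ± 0.059. Heat shock genes (6 and 5, rescaled 3 and 7) went from 0.22 to -0.24, with BOB1 at 1.45 ± 0.077. Stomata and trichome genes (6 and 6, rescaled 6 and 7) went from 0.07 to -0.37, with GL1 at 2.98 ± 0.076 and MYB60 at -2.43 ± 0.065. The floral identity and root lists had 1 tested gene each, LFY (0.97 ± 0.064) and WOX5 (1.34 ± 0.11), both listed at 0 in every leaf library.

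**Figure D1:**
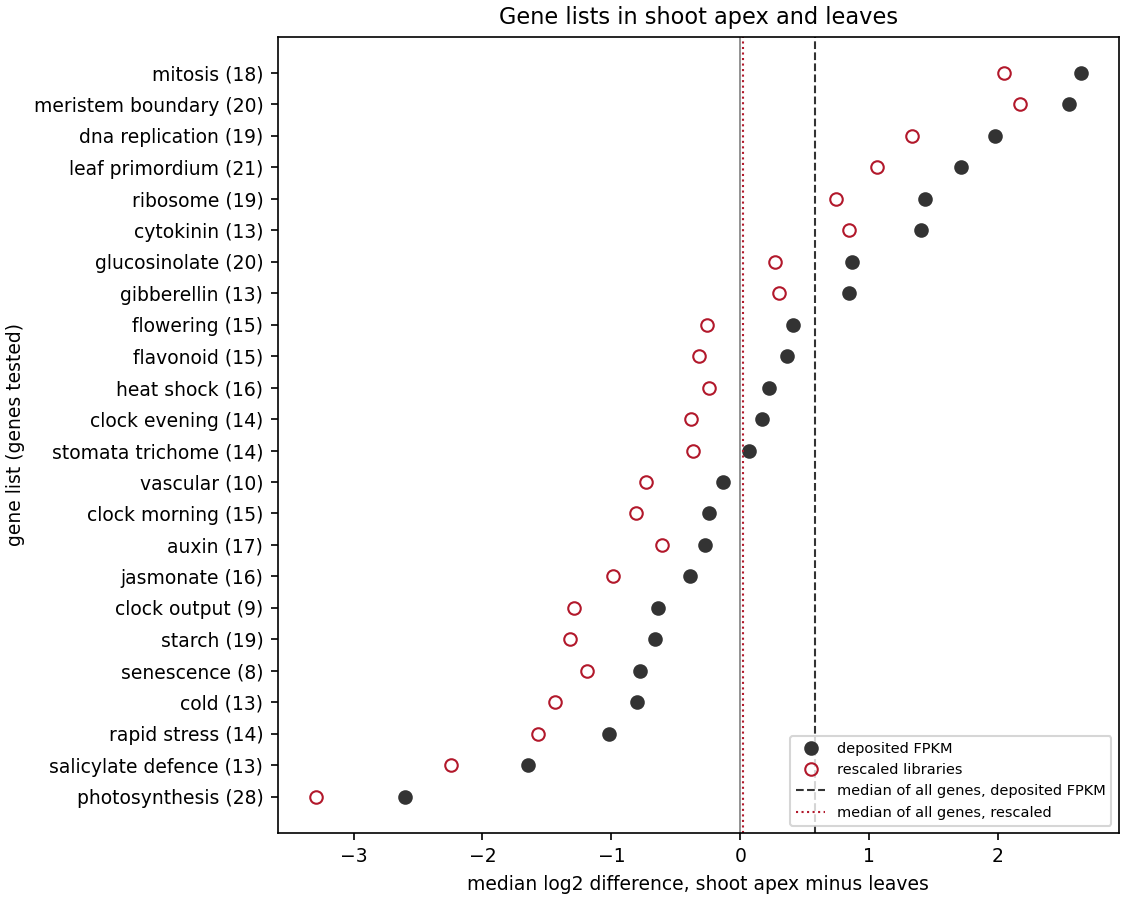
Median log2 difference (shoot apex minus leaves, x axis) of each gene list with more than 1 tested gene (y axis, genes tested in brackets), with filled points for deposited FPKM and open points for rescaled libraries, and vertical lines at 0 and at the medians of all genes (0.58 and 0.023). Mitosis (2.64, rescaled 2.05) and photosynthesis (-2.60, rescaled -3.29) lie at the ends, and the clock evening, flavonoid, flowering, heat shock and stomata lists change sign between the scales.

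In a competitive test against all other genes (limma camera with a preset correlation of 0.01 between genes), 14 of 26 lists passed. The 4 toward the shoot apex were meristem and boundary (adjusted p = 0.000123; 0.306 with an estimated correlation), DNA replication (0.000123; 0.341), ribosome (0.000167; 0.396) and mitosis (0.00037; 0.443). The 10 toward leaves were photosynthesis (adjusted p = 4.02e-25; 0.285 with an estimated correlation), starch (3.86e-08; 0.306), rapid stress (1.7e-05; 0.312), salicylate defence (0.000123; 0.443), and clock morning (0.000144; 0.285). Less clear were cold (0.000944; 0.443), jasmonate (0.00312; 0.443), clock output (0.00376; 0.285), vascular (0.00692; 0.341) and senescence (0.0128; 0.322). The median of each of these 14 lists had one sign in both replicate numbers. With an estimated correlation, limma camera passed 0 lists, and 4 had an unadjusted p under 0.05. After rescaling, clock evening (down, adjusted p = 0.0263) and leaf primordium (up, 0.0287) also passed, while cold (0.0576) and senescence (0.195) did not. Counts of members adjusted over the list alone were the same as those over all genes in all 26 lists.

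The salicylate and defence genes were higher in the leaves of replicate 1 than of replicate 2. PR1, a pathogenesis-related gene and the list member that did not pass the tissue test, was at 221 ± 121 FPKM in leaves of replicate 1 and 7.57 ± 12.9 in replicate 2. It was at 18.9 ± 10.6 and 2.57 ± 2.62 in the shoot apex (SD, n = 6 each). PR1 passed without leaves ZT90 replicate 2, leaves ZT94 replicate 2 or leaves ZT106 replicate 2, with the replicate block and after rescaling, with log2 differences of -2.62 to -1.44 without 1 library. PR2 was at 227 ± 112 and 14.6 ± 17.5 FPKM in leaves, and the salicylate synthesis gene ICS1 at 19.2 ± 5.15 and 5.04 ± 1.2. All 13 genes were higher in replicate 1 of leaves, with a median log2 difference of 1.72 (limma camera adjusted p = 1.15e-13; 0.0822 with an estimated correlation). The list's tissue difference had a median of -2.43 in replicate 1 and -0.88 in replicate 2.

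**Figure D2:**
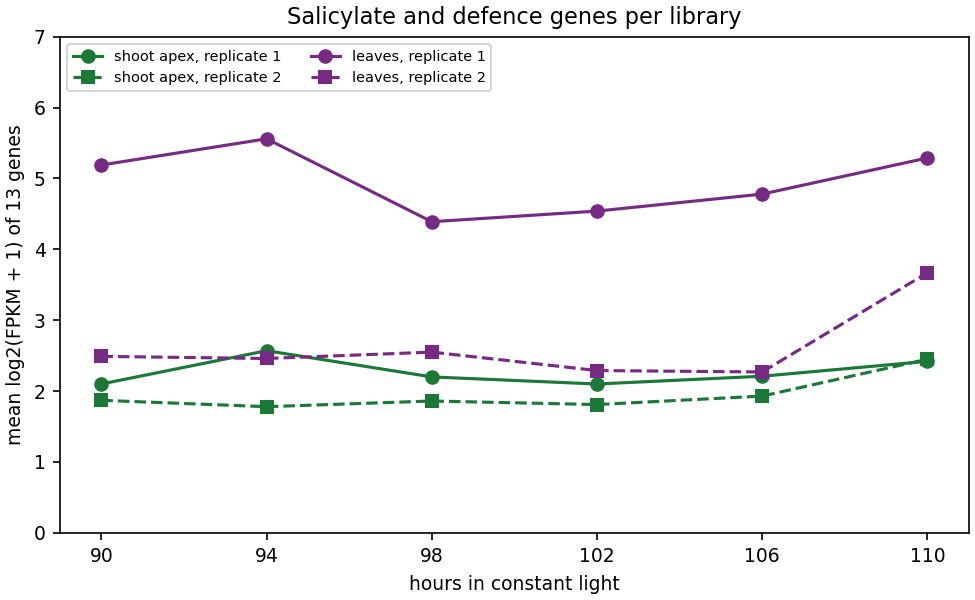
Mean log2(FPKM + 1) of the 13 salicylate and defence genes (y axis) in each library against hours in constant light (x axis), coloured by tissue, with circles and solid lines for replicate 1 and squares and dashed lines for replicate 2. Leaf libraries of replicate 1 lie at 4.39 to 5.56 and those of replicate 2 at 2.27 to 3.67, and shoot apex libraries at 1.78 to 2.57.

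Core clock transcripts oscillated in both tissues between 90 and 110 h of constant light. CCA1, a morning repressor of the clock, had an amplitude of 2.24 ± 0.077 with a peak at 22.86 h in the shoot apex and of 2.18 ± 0.077 with a peak at 0.28 h in leaves. Its partner LHY had amplitudes of 2.47 ± 0.098 and 2.21 ± 0.098 with peaks at 22.03 and 23.19 h, and the coactivator gene LNK2 amplitudes of 2.03 ± 0.091 and 2.18 ± 0.091. Of the evening genes, the blue light receptor gene FKF1 had amplitudes of 2.14 ± 0.11 (peak 10.1 h) and 1.97 ± 0.11 (peak 10.74 h), and JMJD5, a demethylase gene, 2.1 ± 0.094 and 2.35 ± 0.094. Of 29 clock genes of morning and evening, 26 passed the rhythm test in both tissues (limma, 24 h wave), and LKP2, ZTL and RVE6 passed in neither. TCP21, 1 of the 26, lost its shoot apex call without any of 16 of the 24 libraries, with a pseudocount of 0.1 and after rescaling. The output genes PIF4 and GRP7 cycled with amplitudes of 1.95 ± 0.13 and 1.70 ± 0.12 in the shoot apex and 1.93 ± 0.13 and 1.96 ± 0.12 in leaves. CONSTANS (CO), a flowering regulator, had an amplitude of 0.51 ± 0.082 in the shoot apex (adjusted p = 0.000561) and 0.017 ± 0.082 in leaves (adjusted p = 0.99), and the difference itself passed (adjusted p = 0.0139).

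**Figure D3:**
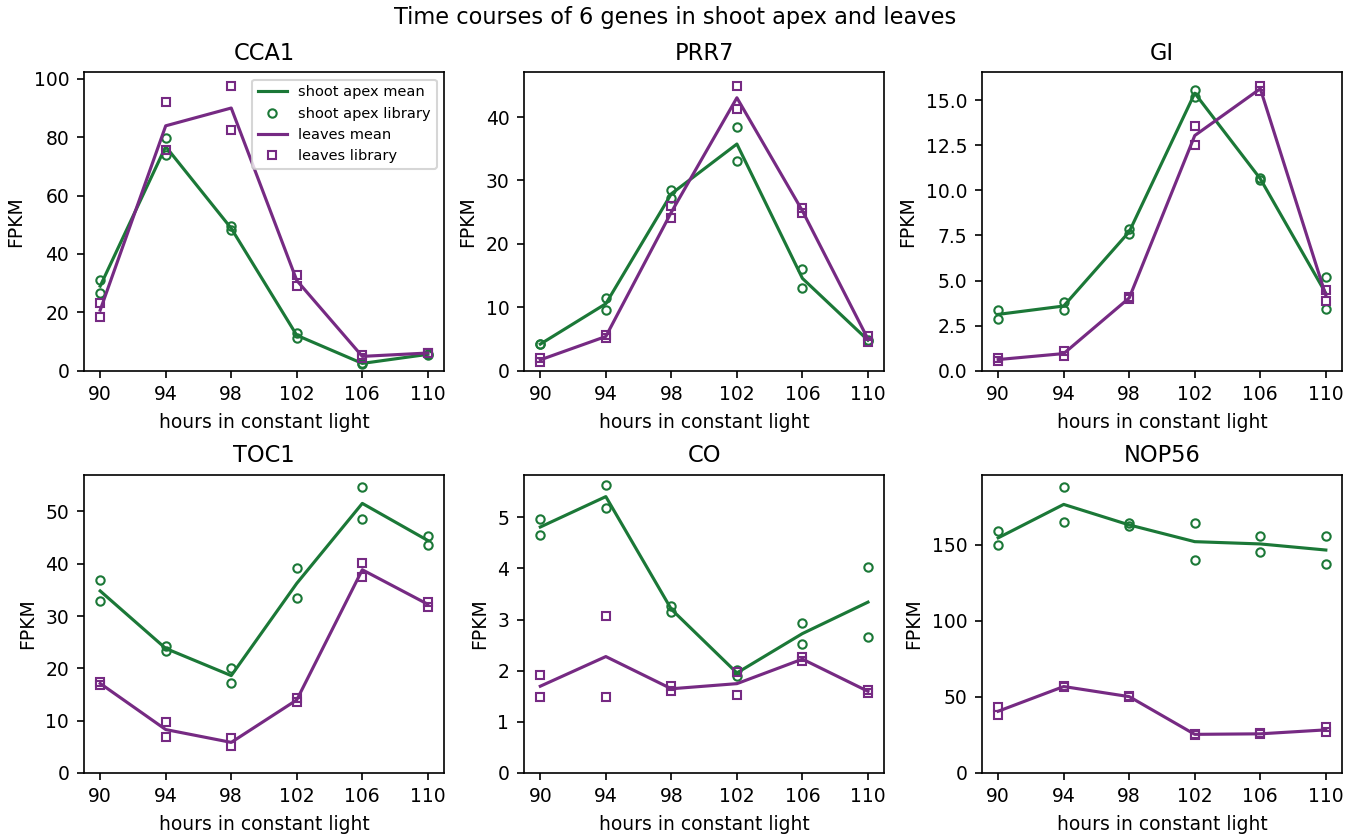
FPKM (y axis) of 6 genes in each library (circles shoot apex, squares leaves) and their means (lines, n = 2 per point) against hours in constant light (x axis). The fitted peaks of CCA1, PRR7 and GI came 1.42, 1.37 and 1.37 h earlier in the shoot apex, CO varied in the shoot apex, and NOP56 varied in leaves.

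The light harvesting gene LHCB1.1 had an amplitude of 2.69 ± 0.23 in the shoot apex (peak 2.29 h) and 2.25 ± 0.23 in leaves (peak 2.88 h), and LHCB2.3 of 2.03 ± 0.19 and 2.13 ± 0.19, and neither differed in rhythm between tissues (adjusted p = 0.516 and 0.402). LHCB1.2 had 2.01 ± 0.14 and 1.86 ± 0.14 and peaked at 2.67 and 4.6 h, a difference of -1.92 ± 0.38 h (adjusted p = 0.00612), with the division of reads among LHCB1 copies uncertain. In leaves the kinase gene CIPK20 (2.42 ± 0.13, peak 4.18 h), the cold response gene COR15B (2.31 ± 0.31, peak 11.72 h) and the anthocyanin repressor gene MYBL2 (2.28 ± 0.14, peak 5.31 h) were among the 8 widest under the naming rule. In all, 2608 genes (13%) passed the rhythm test in the shoot apex and 8175 (40.9%) in leaves, and 1955 passed in both where independent lists would share 1067. Both tests of a gene use 1 error shared by the tissues, which can raise this overlap by itself, and how far was not tested. With the replicate number as a block within each tissue, an alternative chosen after seeing the data, the shoot apex count was 4182 and held all 2608. Amplitudes of at least 0.5 were fitted for 509 of the passing genes in the shoot apex and 1592 in leaves. The shoot apex count was 2013 without replicate 1 and 956 without replicate 2, and the leaf count 7158 and 5938.

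Peak times are given as shares of rhythmic genes, and their spread was not tested between the 2 tissues. In the shoot apex 24.6% of rhythmic genes peaked at 6 to 10 h and 22% at 18 to 22 h, and after rescaling 21% and 23.7%. In leaves 47.7% peaked at 10 to 18 h, which fell to 27.9% after rescaling. The broad leaf maximum thus rested on the deposited scale. After rescaling the fullest leaf bins were 20 to 22 h (11.7%) and 22 to 24 h (14.1%), next to the 18 to 22 h group of the shoot apex.

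**Figure D4:**
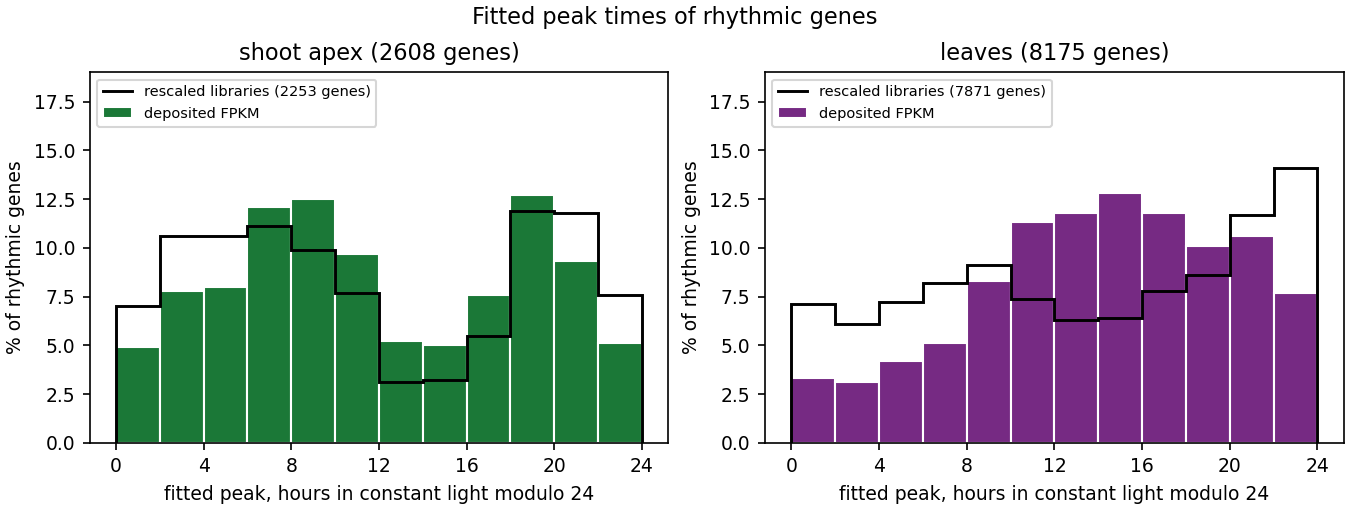
Share of rhythmic genes (y axis, %) by fitted peak time in bins of 2 h (x axis, hours modulo 24), with bars for deposited FPKM and a black outline for rescaled libraries. In leaves the share at 10 to 18 h falls from 47.7% to 27.9% after rescaling, and in the shoot apex from 27.5% to 19.5%.

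Clock genes peaked earlier in the shoot apex than in leaves. The peak of CCA1 came at -1.42 ± 0.19 h relative to leaves, that of PRR7, a daytime repressor gene, at -1.37 ± 0.18 h, and that of GI (GIGANTEA) at -1.37 ± 0.29 h. RVE7 showed a shift of -2.68 ± 0.7 h (-3.13 and -2.32 h in replicates 1 and 2) and RVE4 of -2.64 ± 0.77 h (-4.79 and -1.05 h), while RVE2, PRR5 and COR28 peaked later in the shoot apex (1.4 ± 0.59, 0.6 ± 0.61 and 0.16 ± 0.42 h). Adjusted p for the rhythm difference was 0.0677 for RVE4, 0.0911 for RVE2, 0.669 for PRR5 and 0.132 for COR28. RVE4 passed without leaves ZT106 replicate 2, with the replicate block and after rescaling, RVE2 without leaves ZT90 replicate 1 or leaves ZT94 replicate 2, and COR28 after rescaling. Over the 26 genes the median difference was -0.76 h (range -2.68 to 1.4), and 23 were earlier in the shoot apex. The same number were earlier in both replicate numbers, with medians of -0.84 and -0.8 h. Across all 1955 genes rhythmic in both tissues the median was -0.9 h (-0.79 h after rescaling), 71.8% peaked earlier in the shoot apex, and 83.3% had peaks within 3 h of each other. Samples were taken every 4 h. In simulated data without a replicate difference, a shift of -1 h was recovered as a median of -1.06 h. The median error there was 0.34 h per gene.

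**Figure D5:**
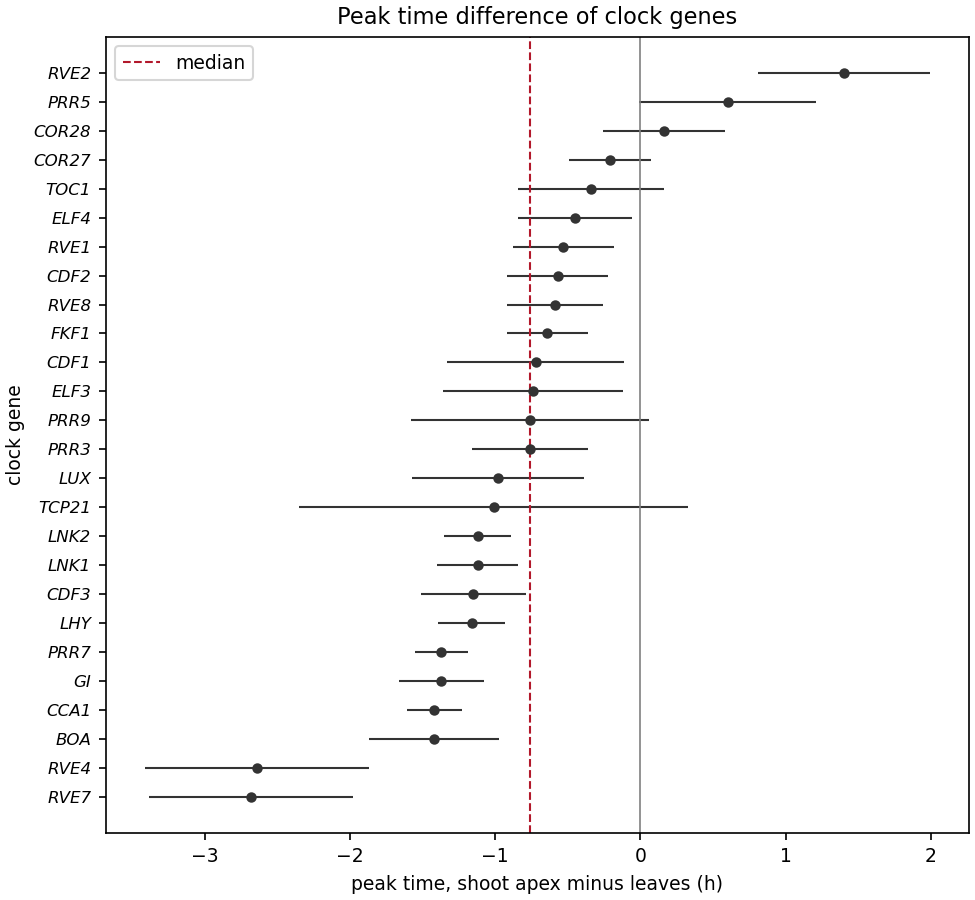
Fitted peak time in the shoot apex minus that in leaves (x axis, h; points, with bars of 1 SE) for the 26 clock genes rhythmic in both tissues (y axis), with the median as a dashed line at -0.76 h. The points of 23 genes lie below 0 and those of COR28, PRR5 and RVE2 above it.

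Amplitudes of clock genes were smaller in the shoot apex in 20 of the 26 genes, with a median difference of -0.248 log2 (range -0.82 to 0.411; -0.22 and -0.276 in replicates 1 and 2). GI had amplitudes of 1.03 ± 0.068 and 1.80 ± 0.068 in the shoot apex and leaves, and TOC1 (an evening repressor gene) 0.66 ± 0.077 and 1.28 ± 0.077. PRR9, at the -0.82 end, had 0.45 ± 0.091 and 1.27 ± 0.091, but its means were 0.374 ± 0.376 FPKM in the shoot apex and 1.83 ± 1.91 in leaves, so the pseudocount of 1 flattens it more in the shoot apex and its SD relative to the mean was about the same in both. ELF4 had 1.90 ± 0.12 and 1.49 ± 0.12, but its rhythm difference did not pass (adjusted p = 0.194). The rhythm itself, amplitude and phase together, differed between tissues for 13 of the 26 (limma; 17 adjusted over the list alone). Adjusted p was 6.69e-06 for PRR7, 1.28e-05 for GI, 0.000181 for CCA1, 0.00243 for TOC1, 0.0027 for RVE7, 0.00365 for LHY, 0.00747 for LNK2 and 0.00988 for CDF3, and 0.000766 for PRR9 with the limit just given. Each of these calls held without any 1 library, which those of the other 4 (ELF3, LUX, BOA and LNK1) did not. The ELF3 call was lost without shoot apex ZT110 replicate 2, leaves ZT98 replicate 1 or leaves ZT98 replicate 2. That of LNK1 was lost without shoot apex ZT90 replicate 1, ZT94 replicate 1, ZT94 replicate 2 or ZT106 replicate 1 or leaves ZT106 replicate 2, and those of BOA and LUX without any of 16 of the 24 libraries each. BOA and LNK1 were also lost with a pseudocount of 0.1 and LUX after rescaling.

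Among named genes with mean FPKM of at least 5 in both tissues, SHA1, a gene of shoot meristem maintenance, and RHM1 had the smallest adjusted p for a difference (1.33e-06 each). SHA1 had an amplitude of 0.028 ± 0.046 in the shoot apex and 0.86 ± 0.046 in leaves (peak 11.17 h). The rhamnose synthesis gene RHM1 had 0.28 ± 0.05 and 1.13 ± 0.05, the zinc finger gene OZF2 0.29 ± 0.061 and 1.07 ± 0.061, and the acetate activating gene AAE7 0.21 ± 0.057 and 0.98 ± 0.057, where the shoot apex rhythm of AAE7 was lost without any of 13 of the 24 libraries. RSR4, a vitamin B6 synthesis gene, had 0.095 ± 0.041 and 0.55 ± 0.041. BAM3 peaked at 13.14 h in the shoot apex and 17.28 h in leaves, the leaf development gene TCP3 at 9.73 and 14.47 h, and the amylase gene AMY3 at 6.52 and 9.02 h. TRX-M4, a plastid thioredoxin gene, had the larger amplitude in the shoot apex (0.51 ± 0.033 against 0.27 ± 0.033). The test called 2127 genes, 1908 with the larger amplitude in leaves and 219 in the shoot apex, and 1826 of those called after rescaling were larger in leaves. Of the 2127, 643 were rhythmic in both tissues, 1347 in leaves alone, 115 in the shoot apex alone and 22 in neither. With the block within each tissue the count was 4034 and held all 2127, and it was 1073 without replicate 1 and 330 without replicate 2.

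Ribosome genes cycled together in leaves. All 19 passed there with a mean peak at 22.7 h, for example FIB1 (fibrillarin) with an amplitude of 0.54 ± 0.044 and NOP56 with 0.62 ± 0.053, against 0.13 ± 0.044 and 0.11 ± 0.053 in the shoot apex, where 1 of 19 passed (0 adjusted over the list alone, limma, with 6 at unadjusted p under 0.05). The rhythm differed for 16 of the 19, also after rescaling, when 4 passed in the shoot apex, FIB1 among them. Starch genes passed in 12 of 19 cases in the shoot apex and 16 in leaves, with mean peaks at 9.4 and 12.7 h. Their peaks were spread, with resultant lengths (1 where all peaks coincide) of 0.7 and 0.52, against 0.99 for ribosome genes in leaves. The rhythm of 12 differed (11 after rescaling), among them the synthase gene SS4 (0.38 ± 0.06 and 0.82 ± 0.06) and GBSS1 (0.93 ± 0.11 and 1.94 ± 0.11). SS1 had the larger amplitude in the shoot apex (0.32 ± 0.032 and 0.19 ± 0.032). Flavonoid genes passed in 13 of 15 cases in each tissue near 19.6 and 20 h, with amplitudes of 1.35 ± 0.14 and 2.11 ± 0.14 for chalcone synthase (CHS) and 1.32 ± 0.12 and 1.72 ± 0.12 for F3H. The rhythm of 9 differed, for example the flavonol regulator gene MYB111 (0.18 ± 0.085 and 0.98 ± 0.085). Photosynthesis genes passed in 24 and 27 of 28 cases, with LHCA1 at 1.17 ± 0.086 and 1.43 ± 0.086. Cytokinin genes passed in 9 of 13 cases in the shoot apex around 21 h (ARR4 0.39 ± 0.046, CKX5 0.37 ± 0.053) and in 8 in leaves. Meristem and boundary genes passed in 8 of 20 cases in the shoot apex around 18.8 h (11 adjusted over the list alone), with CUC3 at 0.47 ± 0.057, KNAT1 at 0.26 ± 0.046 and STM at 0.26 ± 0.05, and in 5 in leaves. With a pseudocount of 0.1 these 3 genes no longer passed. The fit gives each gene a shared error over both tissues. For KNAT1 and STM the very low leaf values hardly vary at a pseudocount of 1, which lowers that error and can ease a shoot apex call. How far this explains the loss was not tested.

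Cold response genes passed in 12 of 13 cases in leaves around 11.3 h (COR413PM1 1.17 ± 0.11, KIN2 2.00 ± 0.22) and in 4 in the shoot apex. Leaves ZT106 replicate 2 stood apart near that peak, with a list mean of 5.77 log2 against 3.65 in replicate 1, and without it 10 of 13 passed in leaves (Fisher exact adjusted p = 0.0235, a check chosen after seeing the data). Glucosinolate genes passed in 11 and 13 of 20 cases around 19.6 and 19.7 h (SOT17 0.62 ± 0.11 and 0.61 ± 0.11), apart from the myrosinase gene TGG1 with a peak at 9.1 h in the shoot apex. That call was lost without shoot apex ZT94 replicate 1 or shoot apex ZT106 replicate 2. Peaks of the glucosinolate list were more spread in the shoot apex (resultant length 0.63) than in leaves (0.87). In leaves, 10 of 17 auxin genes passed (IAA29 1.79 ± 0.12, peak 9.3 h; 1 in the shoot apex), as did 9 of 13 gibberellin genes (GID1A 0.49 ± 0.05; 1 in the shoot apex, GA2OX1 0.73 ± 0.084). So did 10 of 15 flowering genes (SPL3 0.69 ± 0.085; 4 in the shoot apex), 12 of 21 leaf primordium genes (AS1 0.61 ± 0.059; 3 in the shoot apex) and 9 of 16 heat shock genes (HSP101 0.40 ± 0.079; 2). Of jasmonate genes 8 of 16 passed (OPR3 0.63 ± 0.12; 2), with 5 of 8 senescence genes (SEN1 1.74 ± 0.16; 2) and 5 of 19 DNA replication genes (HTR2 0.23 ± 0.052; 1). Few passed in the remaining lists. In the shoot apex limma called 0 of 18 mitosis genes (0 at unadjusted p under 0.05), 0 of 14 rapid stress genes (0), 0 of 13 salicylate defence genes (0), 0 of 14 stomata and trichome genes (2) and 0 of 10 vascular genes (1). In leaves the counts were 1 mitosis gene (CDKB1;1 0.26 ± 0.064, not passing after rescaling), 3 rapid stress genes (TCH4 0.92 ± 0.16), 0 salicylate defence genes (limma; 0 at unadjusted p under 0.05; 8 with the block within each tissue), 2 stomata and trichome genes (TRY 0.83 ± 0.10) and 1 vascular gene (SWEET12 0.83 ± 0.12). WOX5 passed in the shoot apex at 0.41 ± 0.11, but not with a pseudocount of 0.1 or without shoot apex ZT94 replicate 2, ZT98 replicate 2, ZT110 replicate 1 or ZT110 replicate 2, and LFY passed in neither tissue.

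Shares were set against all other genes with 2-sided Fisher exact tests, and 19 of 52 tests of a list in a tissue passed after adjustment. In the shoot apex the adjusted p was 3.39e-16 for photosynthesis (85.7% against 12.9% of other genes), 1.38e-10 for clock morning, 1.75e-08 for clock evening and 9.39e-08 for clock output. It was 4.36e-09 for flavonoid, 3.2e-06 for starch, 2.72e-05 for cytokinin, 5.14e-05 for glucosinolate and 0.00704 for meristem and boundary genes (40% against 13%). The last value carries the limit of the shared error given above. In leaves it was 3.08e-07 for ribosome (100% against 40.8%), 7.09e-09 for photosynthesis, 0.00016 for clock morning, and 0.000734 for cold and for starch. It was 0.00134 for flavonoid, 0.00429 for clock evening and 0.0123 for clock output. Mitosis genes passed toward fewer rhythmic members in leaves (5.6% against 40.9%, 0.00429; 16.7% against 54.2%, 0.00722 with the block within each tissue). Salicylate defence genes also did (0% against 40.9%, 0.00429), but with that block 8 of 13 were rhythmic (61.5% against 54.1%, 0.814), so the low count rested on the difference between leaf replicates. With that block, chosen after seeing the data, 16 tests passed. Clock evening (0.0728), clock output (0.106) and flavonoid genes (0.0506) in leaves and meristem and boundary genes in the shoot apex (0.0616) no longer passed, while cold genes in the shoot apex (0.0314) and stomata and trichome genes in leaves (toward fewer, 0.0186) did. Members of a list are not independent, so these values describe the lists.

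Without a wave shape, an F-test among the 6 time points (limma) called 933 genes in the shoot apex and 4629 in leaves, of which 904 and 4569 also passed the 24 h test. CCA1, PRR7 and GI passed in both tissues. With the block within each tissue the counts were 2647 and 8740. The time course differed between tissues for 532 genes, among them CCA1, PRR7, GI and SHA1 (adjusted p = 0.000954, 0.000554, 0.000458 and 0.000421), and for 2293 with the block. That count fell to 325 without shoot apex ZT94 replicate 1, 326 without shoot apex ZT94 replicate 2, 333 without shoot apex ZT102 replicate 2, 338 without leaves ZT90 replicate 2, 340 without leaves ZT102 replicate 1 and 326 without leaves ZT102 replicate 2.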

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

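Of the tests in this part, those of a collection offset, of the scaling and of single libraries for the clock shift, and the ratio of counts after rescaling, were chosen only after the result was seen, as was the block within each tissue.

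The rhythm differed between shoot apex and leaves for 2127 genes, by a test of the difference itself. In 100 swaps of the tissue labels within pairs of the same time point and replicate number, the highest other count was 694. Only the real labels reached that count (1 of 100, the lowest share that 100 labelings can give), so chance is unlikely. The time course differed for 532 genes by the interaction test, against at most 459 in the other swaps (1 of 100, the real one). Chance is thus unlikely, but the margin was narrow, as the count ranged from 325 to 565 without 1 library. By the same rhythm difference test 13 clock genes, 16 ribosome genes, 12 starch genes and 9 flavonoid genes differed.

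Clock genes peaked earlier in the shoot apex, with a median of -0.757 h. Over the 100 swaps the farthest other median lay 0.873 h from 0. In 3, the real one among them, the median lay at least as far as the real one, so chance is unlikely but not excluded. For the amplitude, -0.248 against 0.201 for the farthest other swap, chance is unlikely as well (1 of 100, the real one). Later collection of one tissue as the whole cause would move the clock genes by a shared shift. Yet 8 of 26 genes (30.8%) lay over 2 SE from the weighted mean shift of -0.96 h. CCA1 and PRR7 were among those below it and COR27 and RVE2 among those above it. The SE rest on a fitted 24 h wave, so this argues against such an offset only as far as that shape holds. Scaling left the median at -0.74 h, and the highest median without any library or replicate number was -0.66 h. A shorter free-running period in the shoot apex, or a phase lead already present under light and dark cycles, may also give the shift, and 1 window of 20 h tests neither. A biological difference between the tissues stays open as a hypothesis.

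Fewer genes passed the 24 h test in the shoot apex (2608) than in leaves (8175). Permuted time labels gave at most 61 and 2273, so chance is unlikely for both (1 of 100 each, the real one). The permutations address any dependence on time, so they do not tell a cycle from a trend. A larger total spread between shoot apex replicates is argued against, since over the 6220 genes called in leaves alone the replicate SD in the shoot apex was 0.88 times that in leaves. With each tissue fitted alone, on its own error, the counts were 2773 and 7018. Both include the difference between replicate numbers, which was broader in leaves (473 genes of at least 2-fold against 41), so they do not compare the remaining scatter. With the block within each tissue, which removes that difference, more genes still passed in leaves than in the shoot apex. Abundant cycling leaf genes that set the FPKM scale are argued against as well, because the leaf count was 3.13 times the shoot apex count on the deposited scale and 3.49 times after rescaling. Cells of different phase mixed in the dissected shoot apex could flatten its waves, which was not tested, and a tissue difference stays open.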

How the results depend on the processing

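The block within each tissue, and the list counts without leaves ZT106 replicate 2, were chosen only after the result was seen. Counts of tissue genes (12155 under the stricter filter to 19966 with no filter), of leaf rhythmic genes (5938 without replicate 2 to 10817 with the block within each tissue) and of 2-fold genes (5069 to 9641) stayed within 1.5 times the main count under every alternative run. Periods of 22 and 26 h gave 2602 and 2389 shoot apex genes. The share of tissue genes higher in the shoot apex was 51% after rescaling and 74.2% to 76.7% with a pseudocount of 0.1, either other filter or the replicate block.

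With the replicate block, time genes in the shoot apex rose to 1484 and time by tissue genes to 1051; it left other counts within 1.5 times. The replicate block within each tissue gave 4182 rhythmic shoot apex genes, 4034 rhythm difference genes, 2647 and 8740 time genes and 2293 time by tissue genes, by removing the replicate difference from the error. Shoot apex rhythmic genes were 956 without replicate 2 (highest 2684 without 1 library), and rhythm difference genes 1073 without replicate 1 and 330 without replicate 2 (highest 2177). Without replicate 1 the shoot apex count was 2013 with as many samples, so sample number does not explain the gap between 2013 and 956. How far fewer samples explain the fall from the main count, and the cause of the gap, were not tested. Time by tissue genes ranged from 325 to 565 without 1 library.

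The clock amplitude difference was -0.341 with a pseudocount of 0.1, -0.343 after rescaling and -0.311 to -0.2 without 1 library, and the peak difference -0.96 to -0.66 h; the cause was not tested. Gene lists passing were 0 with an estimated correlation and 25 with fry, which tests another question. After rescaling the tissue sign reversed for CLV1 (-0.59), ISA3 (-0.03), DPE1 (-0.47), PRR7 (-0.46), GRP8 (-0.14), XCP1 (-0.27), CESA7 (-0.21) and CESA8 (-0.32), as the median of all genes moved from 0.58 to 0.023.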

Other observations

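Of the tests in this part, those of single leaf libraries and of touch at harvest were chosen only after the result was seen.

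Some genes rhythmic in both tissues peaked over 6 h apart, 62 in all. Chosen after their values were seen, the plastid peroxiredoxin gene PRXQ peaked at 8.43 h in the shoot apex and 16 h in leaves, and the ferredoxin reductase gene FNR1 at 7.02 and 15.23 h (amplitudes 0.16 ± 0.038 and 0.25 ± 0.038). The shoot apex call of FNR1 was lost without shoot apex ZT90 replicate 2.

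Salicylate and defence genes were higher in all 6 leaf libraries of replicate 1 than in any leaf library of replicate 2 (lowest 4.39, highest 3.67, list mean in log2), which argues against a few leaf libraries as the cause. Scaling is argued against because 99.4% of the replicate difference (2.34) was kept after rescaling (2.32). Touch and wounding at harvest cannot be told apart from it: rapid stress genes were higher in replicate 1 of leaves at 5 of 6 time points, but by a mean of 0.31 with an SD of 0.72, and 5 of 14 passed as higher there (median 0.06, limma camera adjusted p = 0.625). Jasmonate genes, which also respond to wounding, were higher in replicate 1, 8 of 16 in leaves (median 0.43, 0.00107; 0.295 with an estimated correlation) and 9 of 16 in the shoot apex (0.38, 0.000737; 0.761). If a replicate number is an experiment, growth conditions or a pathogen in 1 of the experiments may be the cause, and no value decides among these.

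The replicate numbers differed broadly in both tissues (limma, adjusted p under 0.05). In the shoot apex 3127 genes were higher in replicate 1 and 1004 in replicate 2, and in leaves 4011 and 2127. Differences of at least 2-fold were found for 41 genes in the shoot apex and 473 in leaves. The list values that follow are for leaves. Leaf mitosis genes were higher in replicate 2 in 18 of 18 cases (median -0.41, replicate 1 minus 2; limma camera adjusted p = 2.43e-13, 0.0692 with an estimated correlation), and 11 of 16 heat shock genes were higher in replicate 1 (0.41; 6.86e-05, 0.0601). Of leaf primordium genes 13 of 21 (-0.21; 4.39e-06, 0.0822) and of photosynthesis genes 9 of 28 (-0.19; 2.38e-05, 0.485) were higher in replicate 2. The ribosomal RNA locus AT3G41768 stood at 5800 FPKM in shoot apex ZT90 replicate 2 (1.31% of that library), with 335 as the next highest value and 54 as the lowest. Below 1 FPKM in every library were 7 of 8 floral identity genes and 11 of 13 root genes.

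For the counts of the tissue comparison, swaps of the tissue labels gave at most 17151 genes against 18003, and at most 5392 against 7317 over 2-fold. The real labels ranked first in both (1 of 100 each). Splits that leave most pairs in place still part the tissues, so these swaps cannot decide on chance for the counts. For the 14 gene lists of the tissue comparison chance cannot be excluded, since 40 of 100 splits passed as many and the highest passed 17. Permuted time labels gave at most 6 list tests against 19, and at most 18 and 1353 time genes against 933 and 4629 in the shoot apex and leaves. For these, chance is unlikely (1 of 100 each, the real one).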
